A study of Mus musculus with 4 samples.

How the data were processed

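Liver RNA of male C57BL/6J mice at 4, 8, 13 and 21 months was measured on 4 oligonucleotide arrays with 25-base probes grouped into probe sets. Per the labels, RNA was extracted with Trizol and labelled with biotin, and per the series description the RNA of 6 mice was pooled at each age. Groups were taken from the labelled age, which gives 4 groups of 1 array.

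The deposited values are log2 expression values of 45101 probe sets, from 1.22 to 13.7, with 2 decimals. Per the submitters' processing notes they were made with RMA, which corrects background, normalizes between arrays and summarises the probes of a set on the log2 scale. The version of RMA, the probe set definition and the set of arrays that were normalized together are not given in the sources used here. The quantiles of the 4 arrays were close but not identical, with 75th percentiles of 5.72, 5.72, 5.72 and 5.74. RMA brings the distributions of arrays together, so a shift of most genes in 1 pool would not be visible, and it compresses differences of dim probe sets. No detection calls were used here, so a value near the low end of the range cannot be told from background.

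Probe sets were named through the platform annotation. Of all probe sets 64 were controls, 34945 had 1 gene symbol, 932 had several and 9160 had none or were not listed. Of those with 1 symbol, 34741 were matched by gene identifier to a current gene table of the GRCm38.p6 assembly, which changed 0 symbols, and 204 kept the annotated symbol. No coordinates are given because the files name no genome build. Where a gene had several probe sets, which held for 9010 of 18193 genes, the probe set with the highest mean over the arrays was used. Genes whose mean was at or above 3.74, the median of the probe set means, were kept, which left 11587 genes. Probe sets with several symbols or none entered no gene count or gene list.

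No test was run. With 1 array per age no pair of ages can be tested. A linear trend on age would leave 2 residual degrees of freedom over the 4 arrays and was not run. Genes were counted by a fixed rule of size, at least 2-fold higher or lower, for 8 vs 4, 13 vs 8, 21 vs 13 and 21 vs 4 months, with 13 vs 4 and 21 vs 8 months beside them. Genes whose expression moved in 1 direction at every step were counted too. Each of 32 gene lists and 15 lists of cell type markers, fixed before the data were examined, was described by the number of members at least 1.5-fold higher or lower, the median log2 difference, and the percentile of that median among 10000 random lists of the same size matched on 20 bins of mean expression. A list with at least 5 measured members was said to stand apart below percentile 2.5 or above 97.5. This gave 45 lists and 180 values, and the percentile describes these arrays only. The erythroid list, with 3 members above the filter, and the kidney and mesothelium list, with 4, were too short to describe. Of the kept genes Cidea, Cyp7b1, Fabp4, Foxo1 and Slco1a1 are in more than 1 list.

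Genes named in the text were chosen by a rule fixed in advance. It took the 12 largest higher and 12 largest lower differences at 21 vs 4 months, the 5 largest each way for each step between ages, the 6 largest each way among genes that moved in 1 direction at every step, up to 4 members of each list that stood apart, and the sex-linked and control genes. A gene with another probe set at least 1.5-fold in the opposite direction was to be named only with that said, and there was none. Genes named outside this rule were chosen after their values were seen. They are list members given to show the range of a list, the genes singled out at 8 months, and members of gene families.

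Array quality was described from control probe sets. The 3′ minus 5′ difference of Gapdh and β-actin is a measure of RNA integrity. The 9 hybridisation spike-in probe sets deviated from their own means by -0.01, 0.00, 0.11 and -0.10 at 4, 8, 13 and 21 months.

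Alternatives were the mean over all probe sets of a gene, no filter, a filter at the 75th percentile or on the highest value, centring on the median, quantile normalization, cyclic loess, thresholds of 1.5-fold and 3-fold, steps of at least 0.1, leaving out the 8-month or 13-month array from the ordered counts, random lists matched on 10 bins or not matched, and the mean in place of the median. The comparison of 21 months with the mean of the 3 younger arrays was added after the data were seen. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1, the last only for the alternative normalizations.

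The counting and list steps were tested on simulated data. For 21 vs 4 months, with 11587 genes, 2000 random lists per list and simulated noise of 0.1, all 50 genes raised 2.5-fold, all 50 raised 4-fold and all 50 lowered to 0.4 of their level passed the 2-fold rule. None of 50 raised 1.5-fold and 0 of 11387 unchanged genes did. Of 100 unchanged lists of 20 genes 3 stood apart, and 100 of 100 lists shifted by 0.2 did. The simulated noise was a chosen value, since these data hold no replicate spread. Observed differences between arrays had standard deviations from 0.18 to 0.27. The noise was independent between genes, so false calls of lists whose genes vary together were not tested.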

Results

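Livers of male C57BL/6J mice, an inbred laboratory strain, were profiled at 4, 8, 13 and 21 months of age. The mice ate a low-fat diet without restriction. At each age the liver RNA of 6 mice was pooled and hybridised to 1 oligonucleotide microarray, so 4 arrays cover the 4 ages. The question was how expression in the liver differs between ages from young adulthood to old age. There are no replicate arrays, so no test between a pair of ages could be made. A trend on age over the 4 arrays was not tested and no p-value is given. The spread between mice is unknown, and each difference below is a size measured between pools. The number of arrays limits the precision. All values are on the log2 scale, where a difference of 1 is 2-fold.

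Each array held 45101 probe sets, and 11587 genes passed the filter on level. The array medians were 3.75, 3.76, 3.75 and 3.73 at 4, 8, 13 and 21 months. The pools were close to each other over all probe sets. Across probe sets, which are not independent replicates, Pearson's r was 0.996 for 8 vs 4 months, 0.996 for 13 vs 8, 0.996 for 21 vs 13 and 0.995 for 21 vs 4. The Gapdh 3′ probe set lay 0.11 to 0.21 above its 5′ probe set, and the β-actin pair differed by 1.01 to 1.16, a narrow range over the 4 ages. The label male was checked with sex-linked genes. Xist, which is transcribed from the inactive X chromosome of females, was at 4.47, 4.47, 4.56 and 4.47. The Y-linked gene Eif2s3y was at 7.13, 7.19, 7.26 and 7.23, Kdm5d at 4.99, 4.93, 4.98 and 5.03, and Uty at 5.12, 5.02, 4.89 and 4.80.

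The differences between ages were few at 8 and 13 months and more numerous at 21 months, and most were toward higher expression. At 8 vs 4 months 12 genes were at least 2-fold higher and 3 at least 2-fold lower. At 13 vs 8 months the counts were 15 and 9, and at 21 vs 13 months 36 and 6. At 21 vs 4 months 65 genes were at least 2-fold higher and 4 lower. Beside these, 13 vs 4 months gave 21 and 6, and 21 vs 8 months gave 109 and 15. Of the 65 genes higher at 21 vs 4 months, 15 had another probe set above the filter, and in 13 of the 15 another probe set was at least 1.5-fold higher too. Comparisons share arrays. The 8-month array enters 8 vs 4 and 13 vs 8 with opposite signs, and the 21-month array enters 21 vs 13 and 21 vs 4 with the same sign, so a chance deviation of 1 pool gives opposite or like differences in both.

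**Figure D1:**
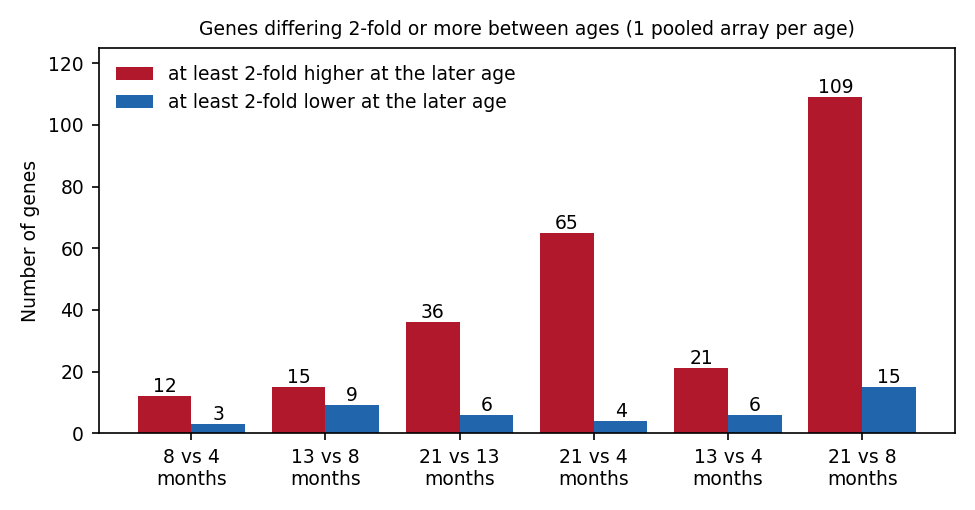
Number of genes at least 2-fold higher (red) or at least 2-fold lower (blue) at the later age, for each pair of ages on the x axis, among 11587 genes. From 1 pooled array per age, 21 months gave 65 higher and 4 lower against 4 months and 109 higher and 15 lower against 8 months.

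The comparison of 21 with 4 months addresses the whole span of age. Several of the large differences were in acute phase genes, which the liver expresses strongly during inflammation, and Lcn2 and Saa2 had the largest of all kept genes. Lcn2, an iron-siderophore binding protein, went from 4.88 to 9.78, which is 29.9-fold. The serum amyloid genes Saa2 and Saa1 were 24.3-fold and 12.1-fold higher, and Orm2, which encodes an orosomucoid, was 14.1-fold higher. The metallothioneins Mt2 and Mt1 were higher by 2.19 and 1.78, and Orm3 by 2.07. All 26 measured acute phase genes were higher at 21 months, 12 of them at least 1.5-fold, and the median difference was 0.54. Several members differed little, among them Crp with 0.08, Fga with 0.12 and Hamp, which encodes the iron hormone hepcidin, with 0.13. The median lay at percentile 100 of 10000 random gene lists of the same size and expression level. This percentile describes these 4 arrays and is not a p-value, and genes of a list can move together for reasons that random lists do not hold. Markers of neutrophils were measured beside them. S100a8 and S100a9, abundant in neutrophils, were higher by 1.35 and 1.45, Prtn3 by 2.73 from a 4-month level below the filter, and Ngp by 0.19, and the median of the 7 markers above the filter was 0.28 (percentile 99.9).

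Markers of macrophages, including the resident Kupffer cells of the liver, were also higher at 21 than at 4 months. Of 20 measured markers 14 were at least 1.5-fold higher and none at least 1.5-fold lower, with a median of 0.72 (percentile 100). Mpeg1, a pore-forming protein of macrophages, was higher by 1.39, Lgals3 by 1.12, the Kupffer cell gene Cd5l by 1.03 and Timd4 by 0.98. Cd163, a hemoglobin scavenger receptor, was lower, at -0.34. Genes of antigen presentation followed the same direction, with all 15 measured members higher, 8 of them at least 1.5-fold, and a median of 0.59 (percentile 100). The class II genes H2-Ab1 and H2-Eb1 were higher by 1.21 and 1.16, and the class II invariant chain Cd74 by 1.08. Interferon response genes had a median of 0.49 (percentile 100), and 13 of 27 were at least 1.5-fold higher, led by Rtp4 with 1.21, Gbp3 with 1.12, Ifi27l2a with 1.09 and Irf7 with 1.03. Of 20 inflammatory cytokine, chemokine and adhesion genes 5 were at least 1.5-fold higher, with a median of 0.28 (percentile 100). The neutrophil attractant Cxcl1 was higher by 1.45, Vcam1 by 0.94 and Cxcl13 by 0.85. B cell and plasma cell markers had a median of 0.34 (percentile 100) over 8 genes. Jchain, which joins IgM and IgA subunits, was higher by 1.58 and Ighm by 2.84, but the mean over all probe sets of Ighm differed by 0.48, and the B cell gene Cd22 was at -0.01. Hepatocyte markers had a median of 0.01 (percentile 45.4), sinusoidal endothelium markers 0.03 (percentile 57.6) and platelet markers -0.03 (percentile 39.0).

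**Figure D2:**
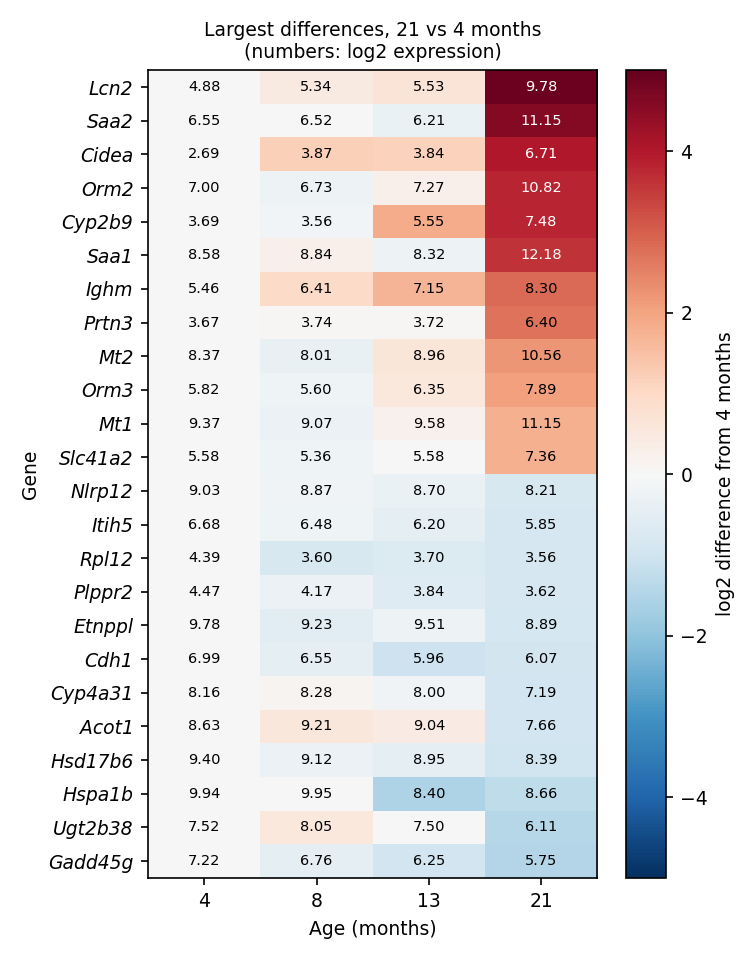
Log2 expression at 4, 8, 13 and 21 months (x axis) of the 12 genes with the largest higher and the 12 with the largest lower difference at 21 vs 4 months (y axis), each cell with the value of 1 pooled array and coloured by the difference from 4 months. Lcn2 goes from 4.88 at 4 months to 5.53 at 13 and 9.78 at 21 months, and Gadd45g from 7.22 to 5.75.

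Lipid genes differed in both directions at 21 vs 4 months. Cidea, a lipid droplet protein that enlarges droplets, was at 2.69 at 4 months, below the filter on level of 3.74, and at 6.71 at 21 months. Over 14 lipid droplet and PPAR-gamma target genes the median was 0.17 (percentile 99.9), with Fitm1 higher by 0.70 and the fatty acid transporter Cd36 by 0.62. Against the mean of the 3 younger arrays, a baseline chosen after the data were seen, that median was -0.012. The median at 8 vs 4 months was 0.32. Cholesterol synthesis genes had a median of 0.27 (percentile 100), and 18 of 20 were higher, 2 of them at least 1.5-fold. Sqle, which makes squalene epoxide, was higher by 0.75 and Fdft1 by 0.60. Over 19 fatty acid synthesis genes the median was 0.11 (percentile 99.0), with Thrsp higher by 0.98, the lipogenic regulator Srebf1 by 0.90 and Fasn by 0.66. Genes of fatty acid oxidation and targets of PPAR-alpha were lower, with a median of -0.19 (percentile 0) and 19 of 21 members below their 4-month level. The acyl-CoA thioesterase Acot1 and the ω-hydroxylase Cyp4a31 were both at -0.97, Cyp4a14 at -0.65, Fgf21 at -0.53 and Pdk4 at -0.50. Oxidative phosphorylation genes differed little, with a median of -0.05 (percentile 0.12) and none of 37 past 1.5-fold.

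Genes that differ between the sexes in mouse liver also differed with age. Cyp2b9, a cytochrome P450 expressed mainly in females, was at 3.69, 3.56, 5.55 and 7.48 at the 4 ages. Its levels at 4 and 8 months lay below the filter of 3.74, so the size of its difference is uncertain. Of 13 male-predominant genes 11 were lower at 21 months, 4 of them at least 1.5-fold, with a median of -0.28 (percentile 0). Ugt2b38 was at -1.41, the steroid dehydrogenase Hsd3b5 and the transporter Slco1a1 both at -0.79, and Elovl3 at -0.69. Egfr, another male-predominant gene, was higher by 0.81. Of 24 female-predominant genes listed, 8 passed the filter, with a median of 0.25 (percentile 99.9). Of the 8, 1 was at least 1.5-fold higher, Cyp2b9, and 1 at least 1.5-fold lower, Acot3 at -0.64. Abcd2 was higher by 0.55. The 14 growth hormone and IGF axis genes, some of which help set these sex differences, had a median of 0.03 (percentile 60.7). Members differed in both directions, from Igfbp2 at -0.55 to Socs3 at 0.41, so the median does not describe single regulators. Bcl6 of this list was at 7.04, 5.93 and 7.13 at 8, 13 and 21 months.

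Lists of other functions differed between 21 and 4 months as well. Collagen and matrix genes had a median of 0.19 (percentile 100) over 24 genes, with Vim higher by 0.80, Tgfbi by 0.64 and Col4a1 by 0.45. Collagen genes alone did not stand apart: over the 26 genes whose symbol is Col followed by a number, a set chosen after the data were seen, the median was -0.02 (percentile 31.2), with 11 higher and 15 lower. ER stress genes had a median of 0.18 (percentile 100) and autophagy and lysosome genes 0.09 (percentile 98.4), the latter led by the cathepsin gene Ctss with 0.99. Heat shock genes were lower in 16 of 17 cases, with a median of -0.14 (percentile 0), Hspa1b at -1.28 and Hspa1a at -0.60. Bile acid genes had a median of -0.06 (percentile 0.57), with Cyp8b1 at -0.52 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at -0.41. Insulin, PI3K, mTOR and AMPK signalling genes had a median of -0.06 (percentile 1.39), none past 1.5-fold. Circadian clock genes had a median of 0.12 (percentile 98.8), with Dbp higher by 0.81 and Arntl at -0.24, and the hour of tissue collection is not given in the sources used here. Cell cycle genes had a median of 0.15 (percentile 99.6) but 8 were higher and 6 lower, and the median turned negative with the mean over all probe sets of a gene. The gut and gallbladder markers had a median of -0.17 (percentile 1.47) over 6 genes, which turned positive with no filter on level. No list difference was seen by this rule in any of the 4 main comparisons for gluconeogenesis (-0.04 at 21 vs 4 months), antioxidant enzymes (0.03), p53 targets and senescence (0.04), cytosolic ribosomal proteins (0.06), adipose tissue (0.06) or skeletal muscle (-0.07). The p53 and senescence list had 13 of 21 members above the filter, without Cdkn2a and Cdkn2b, and its member Gadd45a was higher by 1.52. Besides these lists, the lowest single genes were Gadd45g, a stress-induced growth regulator, at -1.47, the retinol dehydrogenase family member Hsd17b6 at -1.01, Cdh1, which encodes E-cadherin, at -0.92, and Etnppl at -0.89. In all, 16 of 45 lists stood apart as higher and 7 as lower, where 2.2 would be expected in either direction if genes of a list varied independently. Genes of a list can vary together, so a difference between 2 pools alone can give more. Calls for ER stress, autophagy, fatty acid synthesis, lipid droplet, cell cycle, clock, female-predominant, bile acid, insulin signalling and gut and gallbladder lists ended under at least 1 other setting, and the other 13 held under each.

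**Figure D3:**
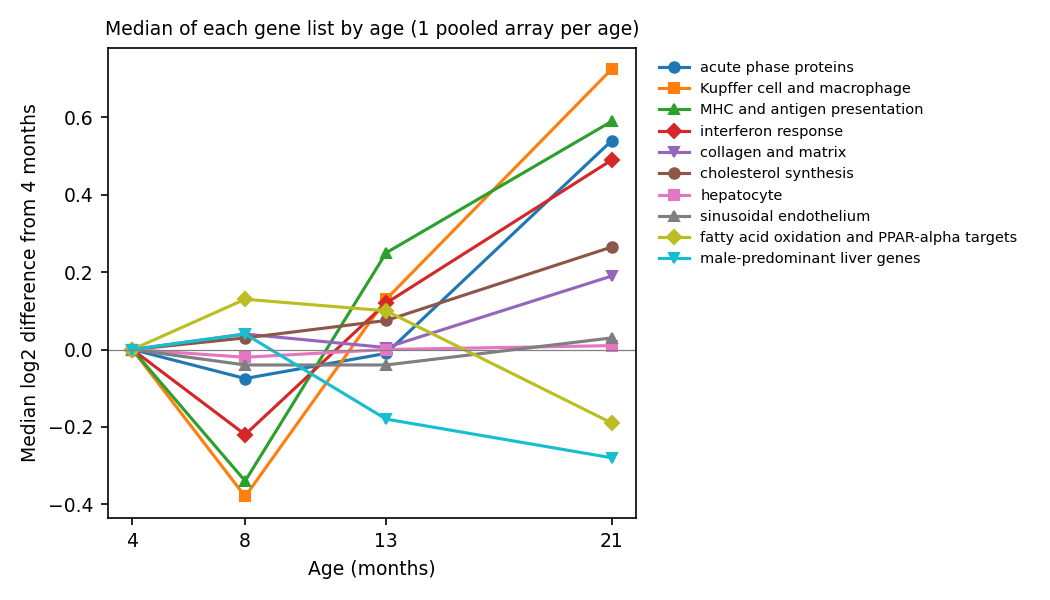
Median log2 difference from 4 months (y axis) of 10 gene lists at 4, 8, 13 and 21 months (x axis), with a line per list and 1 pooled array per age. The macrophage list is at -0.38 at 8 months and 0.72 at 21 months, while hepatocyte and sinusoidal endothelium markers stay near 0.

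The comparison of 8 with 4 months covers early adulthood. Macrophage markers were lower at 8 months in 19 of 20 cases, with a median of -0.38 (percentile 0). Marco, a scavenger receptor of macrophages, was at -1.46, Csf1r at -0.48, and Adgre1 and Cd163 both at -0.47. All 15 antigen presentation genes were lower (median -0.34, percentile 0), as were 26 of 27 interferon response genes (median -0.22, percentile 0), with Usp18 at -0.73. The guanylate-binding protein gene Gbp2b was at -1.16 and ended at 3.22, below the filter on level. Inflammatory genes had a median of -0.12 (percentile 0.18), with Cxcl9 at -0.58, and acute phase genes -0.07 (percentile 0.67), with Hamp2 at -0.77. Urea cycle and amino acid breakdown genes were lower in 13 of 17 cases and higher in 4, with 1 at least 1.5-fold lower. Their median was -0.14 (percentile 0.01), with Tat at -0.66 and Got1 at -0.52. The xenobiotic list had a median of -0.08 (percentile 0.57), with Cyp2b10 at -0.97, the NRF2 and glutathione transferase list -0.11 (percentile 0.05), with Gstm3 at -0.68, and bile acid genes -0.09 (percentile 0.44), with Cyp7a1 at -0.62. Ddit4, an inhibitor of mTOR signalling, was at -1.51, the largest lower difference among the kept genes.

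Higher at 8 than at 4 months were lipid droplet genes, with a median of 0.32 (percentile 100), Cidea higher by 1.18 and G0s2, an inhibitor of fat breakdown, by 0.97. All 21 genes of fatty acid oxidation and PPAR-alpha targets were above their 4-month level, by a median of 0.13 (percentile 100), with Acot1 and Vnn1 both higher by 0.58. Clock genes had a median of 0.17 (percentile 100), with Dbp higher by 1.09 and Ciart by 0.95. Arntl, Nfil3 and Clock, which peak at another phase of the day, were at -0.43, -0.34 and -0.25. The hour of tissue collection is not given, so for any pair of ages a different hour cannot be told apart from age. Whether differences in other lists follow the hour was not tested. B cell and plasma cell markers had a median of 0.31 (percentile 100), T cell and NK cell markers 0.19 (percentile 99.3) and oncofetal genes 0.17 (percentile 98.6). Ighm was higher by 0.95 but by 0.15 as the mean over its probe sets. Among single genes Cd24a was higher by 1.83, the stress-response gene Gadd45a by 1.59, Gnai1 by 1.45 and Ly6d by 1.34. Ltf, which encodes lactoferrin, was higher by 1.94. The 4-month levels of Ltf and Cidea lay below the filter, so the sizes of their differences are uncertain. Small differences were also seen in the gut and gallbladder markers (median 0.17, percentile 97.7, Tff2 higher by 0.55) and the exocrine pancreas markers (median 0.15, percentile 97.6, Zg16 higher by 0.58). Calls for the B cell, T cell, oncofetal, inflammatory, pancreas and gut and gallbladder lists ended under at least 1 other setting, in each case with no filter on level, and the other 11 of 17 held under each.

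Without the filter on level, 8 genes at 8 months were at least 2-fold above every other age, a choice made after their values were seen. Dmbt1, a mucosal scavenger protein, was at 2.35, 7.30, 2.08 and 1.86 at the 4 ages. The others were Chil4, Cd24a, Ltf, the bile duct keratin Krt19, Olfm4, Cxcl5 and Reg1. Krt19 was at 3.48, 4.99, 3.32 and 2.99. At 4 and 13 months no gene met this rule, and at 21 months 23 genes did.

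**Figure D4:**
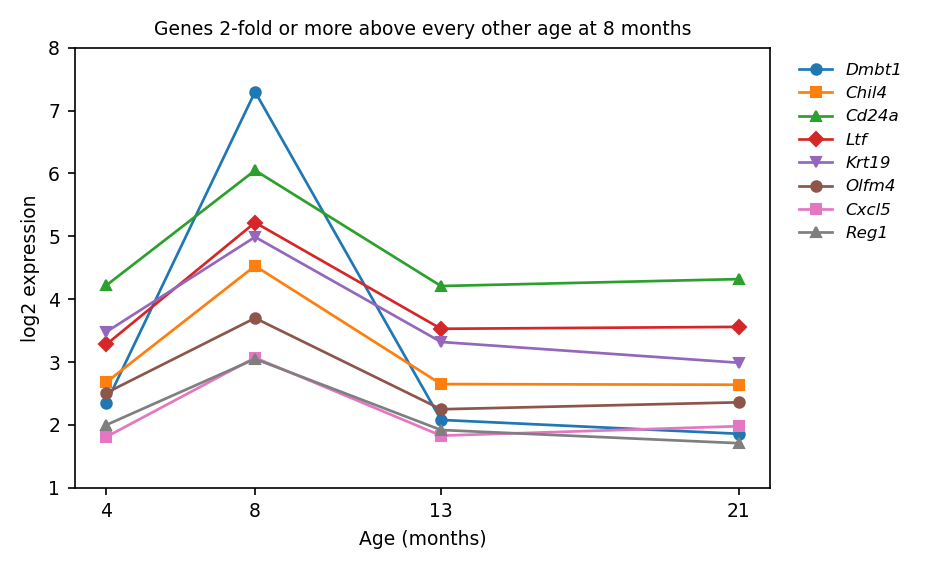
Log2 expression (y axis) at 4, 8, 13 and 21 months (x axis) of the 8 genes at least 2-fold above every other age at 8 months, from 1 pooled array per age. Dmbt1 reaches 7.30 at 8 months and lies at 2.35 or below at the other ages, under the filter on level of 3.74.

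The comparison of 13 with 8 months covers the passage into middle age, and much of it was the mirror image of the step before, with which it shares the 8-month array. Macrophage markers were higher at 13 months in 20 of 20 cases (median 0.46, percentile 100), with Marco higher by 2.33 and Mpeg1 by 0.96. Antigen presentation genes had a median of 0.57 (percentile 100) and interferon response genes 0.38 (percentile 100). The interferon-induced GTPase Igtp was higher by 1.76, Gbp2b by 2.11 from a level below the filter, Zbp1 by 1.24 and Gbp3 by 1.19. Against 4 months the 13-month medians of these 3 lists were smaller, at 0.13, 0.25 and 0.12. Metabolic lists with higher medians were urea cycle and amino acid catabolism (0.16, percentile 100, Got1 higher by 0.63), fatty acid synthesis (0.14, percentile 100, Thrsp higher by 0.74), xenobiotic metabolism (0.12, percentile 99.9, Cyp2b10 higher by 0.61), NRF2 targets (0.11, percentile 99.7, Gsta2 higher by 0.48), sulfur amino acids (0.10, percentile 98.9, Nnmt higher by 0.48) and sirtuins and NAD metabolism (0.10, percentile 98.1, Nampt higher by 0.41). Acute phase genes had a median of 0.11 (percentile 99.9), proteasome genes 0.08 (percentile 98.0) and autophagy and lysosome genes 0.09 (percentile 99.2). Cyp7a1 was higher by 1.06 while the median of the bile acid list was -0.03 (percentile 2.1).

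Sex-biased genes differed between 13 and 8 months. All 13 male-predominant genes were lower (median -0.28, percentile 0), with Hsd3b5 at -0.97, Egfr at -0.66 and Elovl3 at -0.57. Female-predominant genes had a median of 0.21 (percentile 99.8), with Cyp2b9 higher by 1.99, from a level below the filter, and Atp6v0d2 by 1.07. Against 4 months the male-predominant median at 13 months was -0.18 (percentile 0). Lower at 13 months were also ER stress genes (median -0.13, percentile 0, Creld2 at -0.45), heat shock genes (median -0.10, percentile 0.04, Hspa1b at -1.55) and fatty acid oxidation genes (median -0.06, percentile 0.19, Vnn1 at -0.37). Genes that were high at 8 months were lower again, with Cd24a at -1.84, Ltf at -1.69, to a level below the filter, and Ly6d at -1.12 relative to 8 months. Epithelial marker lists were lower, with medians of -0.39 for gut and gallbladder (percentile 0), -0.20 for bile duct cells (percentile 1.73) and -0.17 for exocrine pancreas (percentile 0.94). Serpinb1a was higher by 1.47. The lower gene 1810014B01Rik was at -1.14, but at -0.22 as the mean over its probe sets. Calls for the bile acid, fatty acid oxidation, proteasome, autophagy, sulfur amino acid, xenobiotic, female-predominant and bile duct cell lists ended under at least 1 other setting, and the other 13 of 21 held under each.

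The comparison of 21 with 13 months covers middle to old age, and most of the acute phase difference fell in it. Saa2 was higher by 4.94, Lcn2 by 4.25, Saa1 by 3.86, Orm2 by 3.55 and the lipid droplet gene Cidea by 2.87. Of 26 acute phase genes 14 were at least 1.5-fold higher, with a median of 0.66 (percentile 100). Complement and coagulation genes were higher in 22 of 23 cases, with a median of 0.17 (percentile 100) and none past 1.5-fold. Macrophage markers had a median of 0.60, interferon response genes 0.48, inflammatory genes 0.35 and antigen presentation genes 0.33 (each at percentile 100). Adgre1, the F4/80 antigen of macrophages, was higher by 0.90, and Cxcl1 by 1.63. Neutrophil markers had a median of 0.27 (percentile 99.8), with Prtn3 higher by 2.68 from a level below the filter, and the B cell and plasma cell list 0.20 (percentile 99.5). In that list Jchain was higher by 1.45, Iglv1 by 0.40 and Ighm by 1.15 (0.18 as the mean over its probe sets), while the B cell genes Cd79b and Ms4a1 were at -0.10 and -0.13. Collagen and matrix genes had a median of 0.27 (percentile 100), with Col4a1 higher by 0.70, Col3a1 by 0.69 and Col1a2 by 0.55. Stellate cell markers had a median of 0.12 (percentile 98.7), with 9 higher and 8 lower. ER stress genes were higher by a median of 0.26 (percentile 100), with Dnajb9 higher by 0.59, and cholesterol synthesis genes by 0.15 (percentile 99.9), with Sqle higher by 0.47.

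Fatty acid oxidation genes and PPAR-alpha targets were lower at 21 than at 13 months in 20 of 21 cases, 6 of them at least 1.5-fold, with a median of -0.25 (percentile 0). In that list Acot1 was at -1.38, Pdk4 at -0.98, Fgf21 at -0.82 and Cyp4a31 at -0.81. Clock genes had a median of -0.23 (percentile 0), with Usp2 at -1.02 and Per2 at -0.60, but 5 members were higher, among them Bhlhe40 by 0.63 and Arntl by 0.41. Lower medians were also seen in heat shock genes, -0.10 (percentile 0.33), with Hspb1 at -0.67, and oxidative phosphorylation genes, -0.07 (percentile 0.02), with none past 1.5-fold. Other genes with large lower differences were Acot3, an acyl-CoA thioesterase gene of the female-predominant list, at -1.66, Ugt2b38 at -1.39, the retinoic acid hydroxylase Cyp26b1 at -1.05 and the hepatic transcription factor Onecut1 at -1.05. The call of 1 of the 16 lists, stellate cell markers, ended under at least 1 other setting.

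Ordered differences over the 4 ages were not more frequent than orders drawn at random would give. Expression was higher at every step in 507 genes and lower at every step in 364, together 7.5% of genes, where 8.3% of all orders of 4 values run in 1 direction. Of these, 16 genes were at least 2-fold higher over the whole span and 2, Gadd45g and Hsd17b6, at least 2-fold lower. Besides Lcn2 and Ighm, the largest were Igkv8-30, an immunoglobulin kappa variable gene, with 1.57, Wfdc2 with 1.55, the thyroxine-binding globulin gene Serpina7 with 1.42 and Plac8 with 1.39. Itih5, Plppr2, Nlrp12 and Slco1a1 were lower at every step and ended at -0.83, -0.85, -0.82 and -0.79, Plppr2 at a level below the filter. When each step had to be at least 0.1, 40 genes were higher and 15 lower at every step. Without the 8-month array, with fewer steps that had to have the same sign, genes higher at every step numbered 2089 and genes lower at every step 1530. With fewer ages a larger share of all orders runs in 1 direction. These counts therefore cannot be set against the 8.3% and do not show more ordering.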

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

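The tests on pancreas markers, digestive enzymes, endothelial and stellate markers, neutrophil markers, the share of 1 mouse, and the bile duct and gallbladder list without Dmbt1 and the pancreas list without Reg1 were chosen after the result was seen. The further bile duct and gallbladder list and the smooth muscle list were not among the lists fixed before the data were examined.

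Probe sets with several gene symbols or none are data that the comparisons do not use, and some of them differed between 21 and 4 months. Of 3038 such probe sets above the filter, 14 were at least 2-fold higher and 7 at least 2-fold lower at 21 months. The probe set shared by Tgtp1 and Tgtp2, T cell-specific GTPases induced by interferon, went from 6.32 to 9.09, a difference of 2.77. Probe sets shared by immunoglobulin kappa genes differed by up to 1.65. The largest difference, in a probe set with no gene name, went from 6.73 to 3.54.

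The genes Dmbt1, Chil4, Cd24a, Ltf, Krt19, Olfm4, Cxcl5 and Reg1 stood at least 2-fold above every other age at 8 months. A candidate explanation is more bile duct or gallbladder epithelium in the 8-month pool. A further list, not fixed before the data were examined, had 19 such markers, 10 of them above the filter on level. The list includes Dmbt1, which is itself a gene to be explained. Its median excess over the other arrays was 0.19 (percentile 100), and 0.18 without Dmbt1. Of its members 14 were highest at 8 months. The excess was 5.20 for Dmbt1 but 0.04 for Cldn3. Of the lists of the main comparisons the bile duct cell list did not stand apart at 8 vs 4 months (0.14, percentile 90.8) but did at 13 vs 8 (-0.20, percentile 1.73). In it 8 of 13 measured members were highest at 8 months, and Epcam had an excess of 0.01. The gut and gallbladder list stood apart at both steps (0.17, percentile 97.7, and -0.39, percentile 0). The bile duct call at 13 vs 8 and the gut and gallbladder call at 8 vs 4 months ended under at least 1 other setting. Smooth muscle markers left a share of duct or gallbladder wall open, with a median of 0.105 at percentile 97.1, and pancreas markers as a list were higher, with 0.14 at percentile 99.2, and without Reg1 at percentile 98.8. The 14 digestive enzymes of that list were higher by at most 0.34, but 9 of them lay below the filter, so pancreas stays open. Tissue next to the liver taken along in 1 mouse and a change of the bile ducts with age both stay open in a pool of 6 mice, since no mouse was measured singly and a change with age was not tested apart from the pool.

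Macrophage markers were low at 8 and high at 21 months. The median of 20 markers was 1.07 higher at 21 than at 8 months, and 18 were at least 1.5-fold higher. More non-parenchymal cells of every type would move endothelial and stellate markers too, but the median of those 38 genes was 0.065. Under 3 other scalings the smallest of the macrophage medians was 1.01. They were run on values that RMA had already normalized and could change little, so the scaling within RMA was not tested. More macrophages, a change in the macrophages present, and chance differences between the mice of a pool stay open, as does age itself, which was not tested apart from the pool.

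Acute phase genes were high at 21 months. Lcn2 is also a neutrophil gene, but the median difference of 13 neutrophil markers was 0.19 against 4.90 for Lcn2, and over the 5 markers above the filter at both ages it was 0.24 with a highest of 1.45 for S100a9. For these 5 markers this argues against neutrophil RNA as the main source of Lcn2. The other 8, among them Prtn3 with a rise of 2.73, lay below the filter at 4 or 21 months and cannot decide it. The neutrophil list of the main comparisons stood apart as higher (0.28, percentile 99.9), but that median is the value of Ltf, below the filter at both ages. A smaller share of neutrophil RNA stays open. The values could come from 1 inflamed mouse of the 6, in which Saa2 would have to be 141-fold above the 4-month level and Lcn2 174-fold, and no value here excludes that. An inflammatory state shared by old mice and 1 sick mouse in the pool cannot be told apart.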

How the results depend on the processing

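The comparison of 21 months with the mean of the 3 younger arrays was chosen after seeing the data. Differences had no replicate spread, so a count is called moved when it differs by more than 1.5 times. No paired analysis was possible because each age has 1 array. Of the list calls, 11 of 17, 13 of 21, 15 of 16 and 13 of 23 held under every setting for 8 vs 4, 13 vs 8, 21 vs 13 and 21 vs 4 months. Run on values that RMA had already brought together, quantile normalization, cyclic loess and centring on the median moved no count by over 1.5 times. Of the 65 genes higher at 21 vs 4 months, 58, 61 and 58 were shared with them, in the order quantile, loess, centring. Of values of named genes 1360 were the same by this rule and 4 moved, all under the mean over probe sets (Ighm and 1810014B01Rik). That setting left 337 the same, and a gene with 1 probe set could not change under it. The rest came from the scalings above, which could change little. At 8 vs 4 months the list calls on B cells, T cells, oncofetal, inflammatory, pancreas and gut and gallbladder genes ended with no filter on level. Without detection calls, signal over background is unknown for levels below the filter.

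With a 1.5-fold threshold the counts of genes higher and lower were 58 and 41 for 8 vs 4, 83 and 42 for 13 vs 8, 170 and 53 for 21 vs 13, and 244 and 49 for 21 vs 4 months. With 3-fold they were 3 and 0, 4 and 2, 10 and 1, and 13 and 0. These follow from the thresholds. With no filter 20 genes were higher at 8 vs 4 months and 16 lower at 13 vs 8 months, and at the 75th percentile 7 and 4. The mean over probe sets left 5 genes lower at 13 vs 8 months.

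The number of genes higher at every step was 311 at the 75th percentile, 40 with steps of at least 0.1, 2089 without the 8-month array and 1733 without the 13-month array. The number of genes lower at every step was 624 with no filter, 202 at the 75th percentile, 15 with steps of at least 0.1, 1530 without 8 months and 1438 without 13 months. Those also 2-fold higher numbered 10, 56 and 25 with larger steps, without 8 and without 13 months, and 64 at 1.5-fold. Those 2-fold lower numbered 1 with the mean over probe sets and 11 at 1.5-fold.

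Lists standing apart as higher at 8 vs 4 months numbered 4 with no filter and 3 at the 75th percentile, and those lower at 13 vs 8 months 5 at the 75th percentile. Of the single list medians 1680 kept their call or lack of one, 48 that stood apart no longer did under a setting, 54 that did not came to stand apart, and the sign turned for 7. Against the mean of the 3 younger arrays, lipid droplet and PPAR-gamma targets were at -0.012, bile acid genes at 0.017 and clock genes at -0.018 for 21 months. Cell cycle genes at 21 vs 4 months were at -0.02 with the mean over probe sets, and gut and gallbladder markers at 0.005 with no filter. With the mean in place of the median, neutrophil markers at 8 vs 4 months were at 0.22 and adipose markers at 0.21, where Ltf with 1.94 and Cidea with 1.18 are the highest members. Apart from what fewer genes, arrays or steps imply, the cause was not tested.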

Other observations

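The gene families in this part were chosen after the data were seen. Guanylate-binding protein genes, which are induced by interferon and act against pathogens inside cells, were higher at 21 than at 4 months in 6 of 6 measured members, each at least 1.5-fold, with a median of 0.94 (percentile 100). Gbp2b was higher by 1.40, Gbp3 by 1.12, Gbp8 by 0.96 and Gbp6 by 0.91, and all 6 were lowest at 8 months, where Gbp2b and Gbp8 lay below the filter on level, Gbp8 also at 4 months. Genes whose symbol is Ifi followed by a number, several of them also interferon-induced, had a median of 0.95 over 8 members, with Ifi27l2b higher by 1.14, Ifi27 by 1.13 and Ifi47 by 1.05. Ifi30, a thiol reductase of antigen processing, was higher by 0.85. Members of the Ms4a family, of which several are expressed in macrophages, had a median of 0.39 over 9 genes, with Ms4a6b higher by 0.87 and Ms4a4d by 0.75.

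C-type lectin genes were higher in 11 of 14 members, 4 of them at least 1.5-fold, with a median of 0.16 (percentile 99.6), but differed by member. Clec7a, the β-glucan receptor of myeloid cells, was higher at 21 vs 4 months by 1.11, Clec4n by 0.99 and Clec4a3 by 0.75, while Clec4g of sinusoidal endothelium differed by 0.04 and Clec14a by 0.05. Acyl-CoA thioesterase genes were also split. Acot1, Acot3 and Acot2 were at -0.97, -0.64 and -0.43, Acot9 was higher by 0.48 and Acot11 by 0.33, and the median of 11 genes was -0.19. The directions of these family medians were alike under median centring, quantile normalization and cyclic loess. Of 310 families with at least 6 members 28 stood apart as higher and 10 as lower. If genes of a family varied independently, 15.5 would be expected in either direction, and genes that vary together can give more.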
